A study of Homo sapiens with 4 samples.

How the data were processed

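Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on a subclone of MDA-MB-231, an established human triple-negative breast cancer line, with an antibody against the HA tag (Abcam). The labels name PD-L1 as the precipitated protein and give 2 ChIP samples and 2 input samples, numbered 1 and 2. The genotype label is wild type, and how the tag was brought in is not given in the sources used here. The cells were untreated. A few nanograms of precipitated DNA per library went into a NuGEN Ovation Ultralow kit, per the labels' protocols. The design text calls the replicates independent and biological and says that peaks were called for each.

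Each replicate came as 1 list of broad peaks. Bowtie2 2.2.9, MACS2 2.1.1 and hg38 stand in the submitters' processing notes, with no role or order; the thresholds and the settings of the caller are not given in the sources used here. In each deposited list, column 5 holds a score, which in 99.99% of lines was the whole-number part of 10 times the −log10 q in column 9. Column 7 of the deposited lists holds the fold enrichment (a ratio) that the authors' peak caller gave for each peak, and columns 8 and 9 hold its −log10 p-value and −log10 q-value, per the layout of the caller's broad peak format. These are the authors' values per peak. They served to describe, rank or filter peaks within a list, to compare fold between the lists and to derive the implied background defined below. The peak names in the list of replicate 2 contain the word Merge, whose meaning is not given in the sources used here. Reads were not used here, so the depth of the libraries is unknown; the inputs entered only through the caller, and no input peaks were analysed here.

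Peaks on chromosomes 1 to 22 and X were compared. A shared region was the union of peaks that overlapped by at least 1 bp and that held at least 1 peak of each replicate. The overlap was set against 100 placements of the peaks of replicate 1 at random on the same chromosome, outside gene-free stretches of 1 Mb or more, and the one-sided empirical p can then be no smaller than 0.0099; such a p from random relocation, or from random lists, is called a permutation p here. Assembly gaps could not be left out by position, since no genome sequence was used here; the gene-free stretches stood in for them. Genes came from a RefSeq table of GRCh38.p14, the same build as hg38, which gives the start and end of each gene but no strand, exons or sequence. The promoter of the planned analysis was therefore replaced by a window of 1 kb on each side of both gene ends, called a gene-end window here, and shares of exons and introns, GC matching and the 15 planned sequence motifs were not analysed here. Shares of region centres by location were set against the same kind of placements, with a two-sided empirical p.

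For 21 gene lists fixed before the data were examined, the share of protein-coding genes with a shared region in a gene-end window was compared with all other protein-coding genes by Fisher's exact test (two-sided, with 0.5 added to each cell for the odds ratio). The lists were MHC class I antigen presentation, immune checkpoints, NF-kB, interferon signalling, epithelial-mesenchymal transition, endocytosis with PD-L1 trafficking, nuclear transport, lysine acetylation and deacetylation, glycolysis, ribosomal proteins, the proteasome, clustered histone genes, olfactory receptors, keratin-associated proteins, zinc fingers named ZNF, very long fragile-site genes, and markers of basal and luminal breast, leukocytes, hepatocytes and neurons. Shares over gene bodies were set against 10000 random lists matched on gene length in 20 bins, with a two-sided empirical p. Benjamini-Hochberg adjustment ran over the 21 lists, with a threshold of 0.05. Relations across chromosomes were tested with 100000 permutations. The fold and p of each peak give the Poisson background that joins them, called the implied background; it is approximate for broad peaks, whose values are averages.

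The rule for named genes, fixed before the data were examined, took CD274 and its neighbours JAK2 and PDCD1LG2, the 10 genes whose gene ends met the best-ranked shared regions (mean of the ranks of the highest fold in each replicate), the 5 best-ranked regions anywhere, and the best-ranked member of each list, or 3 members where a list passed. Distance to assembly gaps was not applied in this rule, and 1 of the 10 genes is not reported here. Alternatives fixed before the data were examined were a −log10 q of at least 5, the 50% of peaks with the higher fold, a reciprocal overlap of 50%, equal numbers of peaks, each replicate alone, gene-end windows of 500 bp and 5 kb, overlap in place of centres, and merging within 1 kb. Chosen after seeing the data were moves of 20 to 100 kb in place of random placement, and random lists matched on the density of shared regions within 1 Mb of a gene.

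On simulated data built from the 166548 peaks of replicate 1, with 30% of the shorter list planted as shared, the excess over placement recovered 93.2% of the planted overlap, and the ratio with nothing planted was 1.02. With lists of 25 genes drawn from 19974 and a planted share of 65% at gene ends, Fisher's exact test recovered 87.5% of the lists and called 4.5% of lists with nothing planted. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. With 2 replicates and no reads, a region has no error of its own, and Wilson 95% intervals on shares of genes cover counting error only; genes and regions are not independent replicates.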

Results

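Enriched regions across the genome were mapped by ChIP-seq with an HA antibody in MDA-MB-231, a triple-negative breast cancer cell line. There were 2 biological replicates labelled as PD-L1 ChIP, each with an input library. No mock precipitation was analysed here. In all results below, recovery of chromatin without the target therefore cannot be told apart from binding. PD-L1, the product of CD274, is the ligand of the T-cell inhibitory receptor PD-1 and is best known at the cell surface. The labels' question is where in the genome the precipitated protein was found. The lists held 166628 peaks in replicate 1 and 93618 in replicate 2. On chromosomes 1 to 22 and X, there were 166548 and 93591 peaks, which covered 150 Mb (5.24% of the sequence considered) and 70.6 Mb (2.47%). Median peak width was 610 bp in replicate 1 and 636 bp in replicate 2. Enrichment over the caller's background was low in both lists. The authors' fold enrichment had a median of 3.14 in replicate 1, with 5% and 95% points at 2.72 and 3.71, and of 2.27 in replicate 2, with points at 1.95 and 2.84. The lowest −log10 q was 1.30 in both lists, and the median was 1.91 in replicate 1 and 1.80 in replicate 2. Most peaks, and many of the regions named below, thus lay near the lower end of the lists. A −log10 q of 5 was reached by 40 peaks of replicate 1 and 69 of replicate 2.

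The first comparison asked which regions carried a peak in both replicates. The best-ranked shared region lay over the lower-coordinate end of PGK1, the gene of a glycolytic kinase (hg38 X:78103674-78104676), with fold enrichments of 5.70 and 6.23 in replicates 1 and 2. It was followed by a region outside genes at 20:22046690-22046961 (4.62 and 3.11), 328209 bp from PAX1. Next came regions inside CUL4A, a ubiquitin ligase scaffold (13:113250805-113251319, 4.21 and 3.33), inside ECT2L (6:138801935-138802238, 4.24 and 3.18) and inside SFSWAP, a splicing regulator (12:131784038-131788326, 4.20 and 3.15). In all, 45771 shared regions with a median width of 1337 bp were found. Of the peaks of replicate 1, 47824 (28.7%) overlapped a peak of replicate 2, against 11382 on average and 11572 at most over 100 random placements, a ratio of 4.20 (one-sided permutation p = 0.0099, the smallest the placements allow). Of the peaks of replicate 2, 52.0% overlapped replicate 1, against 12.3% by placement. When peaks were moved by 20 to 100 kb, which keeps the neighbourhood, the share expected in replicate 1 was 13.6% and the ratio was 2.11. Whether the list of replicate 2, whose peak names contain the word Merge, was called on this replicate alone is not given in the sources used here; if not, the lists would not be independent. Whether reads at the PGK1 end came from the genome or from a vector with the PGK1 promoter was not tested.

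Fold enrichment in shared regions was weakly related between the replicates. Each region took the highest fold of its peaks in each replicate. Across the 45771 shared regions, log2 fold enrichment in the replicates had a Spearman's rho of 0.0938 and a Pearson's r of 0.0989. Regions are not independent replicates, and no p is given. Only regions that passed in both lists entered, over a narrow range of fold, so agreement of enrichment elsewhere was not measured. The coefficient rho was 0.236 with equal numbers of peaks per replicate and 0.0137 with the 50% of peaks of higher fold. Within single chromosomes rho had a median of 0.00633 and ranged from −0.0918 to 0.252, with 12 of 23 chromosomes above 0. Among the 100 peaks of replicate 1 with the highest −log10 q, 23 (Wilson 95% interval 15.8% to 32.2%) overlapped any peak of replicate 2, against a mean of 12.7 for moved peaks. Of the top 100 of replicate 2, 22 (15% to 31.1%) overlapped replicate 1, against 12.1. The highest counts for moved peaks were 21 and 19. These shares were below those of the whole lists, 28.7% in replicate 1 (13.6% when moved) and 52.0% in replicate 2 (24.9% when moved). Among the top 5000 peaks, 27.2% of replicate 1 (12.7% when moved) and 37.8% of replicate 2 (17.3% when moved) overlapped the other list.

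The 10 strongest peaks of replicate 2 lay, but for 1, in 3 genes that encode accessory subunits of Polycomb repressive complex 2, the histone H3 lysine methyltransferase. JARID2 (6:15246069-15522042) held 10 peaks with a −log10 q of at least 4, with a maximum of 51.3 at a fold of up to 6.38. AEBP2 (12:19404072-19522227) held 7, with a maximum of 44.6 and a fold of up to 12.3. MTF2 (1:93079283-93139076) held 3, with a maximum of 15.8 and a fold of up to 5.93. Of the peaks of replicate 2 ranked by −log10 q, 9 of the top 10, 15 of the top 20 and 17 of the 69 at 5 or more were in these genes. In replicate 1, JARID2 held 34 peaks with a −log10 q of at most 2.47, AEBP2 held 1 (1.89) and MTF2 none. These genes were chosen after their values were seen, by a rule of at least 3 peaks at a −log10 q of at least 4, which no gene met in replicate 1.

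**Figure D1:**
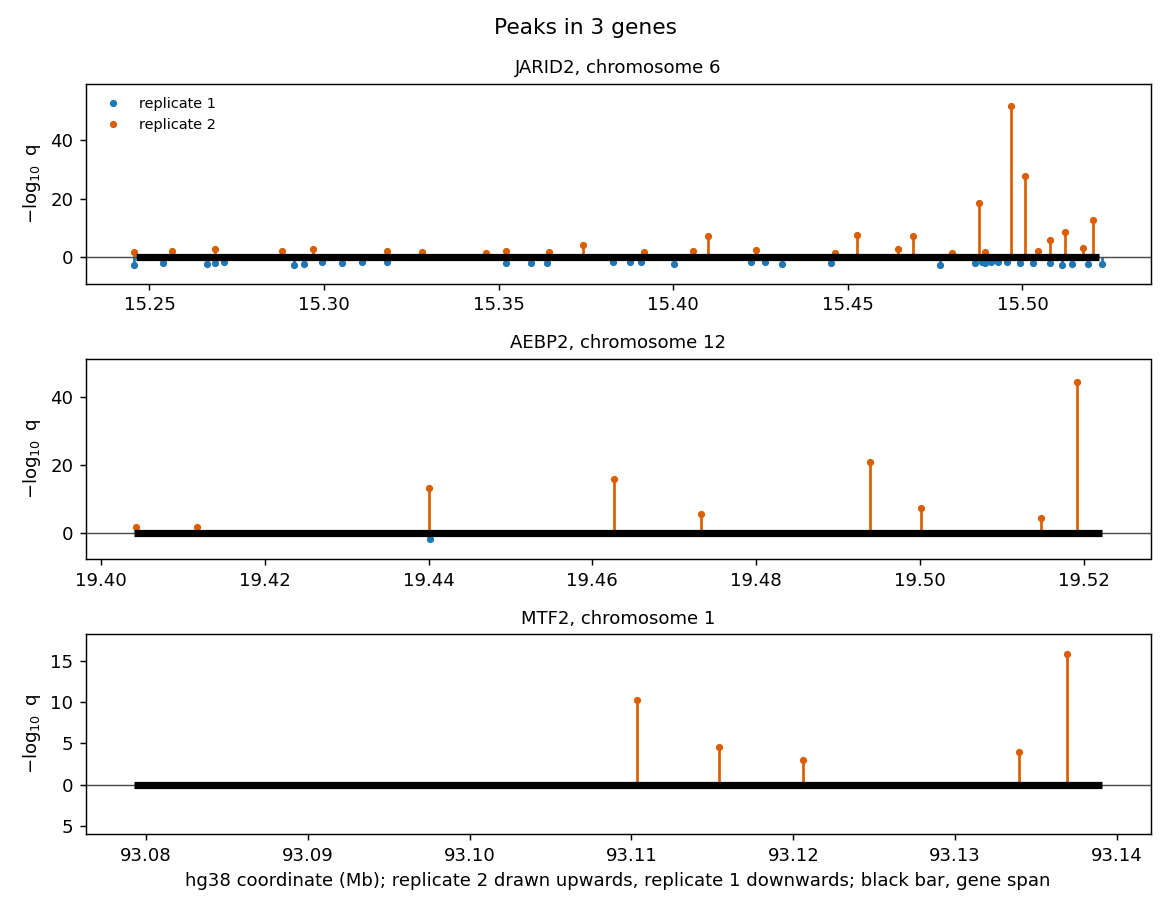
Deposited peaks in and within 1 kb of JARID2, AEBP2 and MTF2, with the hg38 coordinate in Mb on the horizontal axis and −log10 q on the vertical axis (replicate 2 upwards, replicate 1 downwards); each stem is 1 peak at its centre and the black bar is the gene. Replicate 2 reaches 51.3 in JARID2 and 44.6 in AEBP2, whereas replicate 1 stays at 2.47 or lower inside JARID2.

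The second comparison asked where shared regions lay relative to genes. Gene ends were the most enriched location: 9.51% of the centres of shared regions fell within 1 kb of an end of a protein-coding gene, against 3.12% ± 0.0865 by random placement (SD, 100 placements), a ratio of 3.05. A further 53.8% lay inside protein-coding genes, against 45.0% (ratio 1.20). Centres outside genes made up 27.1%, against 38.2% (ratio 0.708), and 9.60% lay only in other genes, against 13.7%. Each had a two-sided permutation p of 0.0198, the smallest possible. Against regions moved by 20 to 100 kb, the enrichment at gene ends was 1.99, and the share inside protein-coding genes no longer differed from the moved share of 54.1% (ratio 0.995, permutation p = 0.139). In several alternatives that share was below the moved share, with ratios down to 0.942. The table of genes gives no strand, so both ends of each gene were counted.

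The best-ranked shared regions at gene ends belonged to 10 genes, of which 9 are described. After PGK1 came CCDC30 and PPIH, a cyclophilin of the spliceosome, which shared the region at 1:42658044-42659452 (fold 3.91 and 3.26 in replicates 1 and 2). FBN2, a fibrillin of extracellular microfibrils, had 5:128258453-128260366 (3.80 and 2.93). SNX30, a sorting nexin, had 9:112750241-112751329 (3.79 and 2.88), and CARNMT1, a carnosine methyltransferase, had 9:75027492-75028661 (4.03 and 2.68). DOCK6, an exchange factor of small GTPases, had 19:11263436-11266399 (3.85 and 2.74). CTNNA1, alpha-catenin of adherens junctions, had 5:138752935-138754399 (3.86 and 2.71), and RHBDL2, a rhomboid protease, had 1:38941237-38942922 (3.87 and 2.70).

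The third comparison asked which gene groups carried shared regions at their ends. Of 19974 protein-coding genes, 6579 (32.9%) had a shared region within 1 kb of either end. Olfactory receptors, keratin-associated proteins, clustered histone genes and ZNF zinc fingers were depleted. Olfactory receptors had 16 of 392 genes with a region (4.08%, against 33.5% of other genes, log2 odds ratio −3.52, adjusted p = 7.96e-45, Fisher's exact test). Keratin-associated proteins, the matrix of the hair shaft, had 1 of 94 (1.06%, −4.95, exact adjusted p = 3.25e-14). Clustered histone genes had 5 of 69 (7.25%, −2.53, exact adjusted p = 3.76e-06), and ZNF zinc fingers had 134 of 509 (26.3%, −0.47, adjusted p = 0.00604). Enzymes of lysine acetylation and deacetylation were enriched, with 15 of 26 genes (57.7%, log2 odds ratio 1.46, exact adjusted p = 0.0459). Against random lists matched on the local density of shared regions, the calls for histone genes (adjusted permutation p = 0.119, with 7.25% against 17.3% in matched lists) and for lysine acetylation (0.176, with 57.7% against 38.9% in matched lists) were lost. In each replicate alone, histone genes passed this matching. They had 34.8% against 62.3% in replicate 1 (adjusted permutation p = 0.00105) and 8.70% against 22.6% in replicate 2 (0.0283). With equal numbers of peaks (0.198), reciprocal overlap (0.93) or the peaks of higher fold they did not. Lysine acetylation passed it in neither replicate alone (0.149 and 0.338). Among all 8 alternatives, the call was lost in 6 for lysine acetylation (adjusted p from 0.0745 to 0.785, exact or permutation, at log2 odds ratios of 0.85 to 1.61) and in 3 for histone genes; for ZNF genes it was lost in 3 and the direction turned in 1.

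Members of the lists that passed, in the order of their rank, were the following. The acetyltransferases KAT6A (fold 3.27 in replicate 1 and 2.57 in replicate 2) and KAT2A (3.98 and 2.22) and the deacetylase SIRT6 (3.41 and 2.34) led the acetylation list. ZNF136 (3.78 and 2.63), ZNF281 (3.74 and 2.56) and ZNF766 (3.92 and 2.49) led the zinc fingers. H3C4 (3.72 and 2.62) led the histones, followed by H2AC6 and H2BC4, whose windows met the same region (3.73 and 2.39). The olfactory receptors with the best regions were OR6F1 (3.34 and 2.50), OR2Y1 (3.49 and 2.29) and OR2L13 (3.16 and 2.56), and the single keratin-associated gene was KRTAP5-9 (2.69 and 2.19).

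At gene ends within 1 kb, none of the lists tied to immune recognition, PD-L1 traffic or cell identity passed. MHC class I antigen presentation had 3 of 18 genes with a region (16.7%, adjusted p = 0.438, Fisher's exact test), among them NLRC5, the transactivator of class I genes (fold 2.98 and 2.31). Immune checkpoints had 4 of 19 (21.1%, adjusted p = 0.64, exact), led by NECTIN2, a ligand of TIGIT (3.34 and 2.08). NF-kB genes had 9 of 28, led by RELB (3.66 and 2.51), and interferon signalling had 10 of 30, led by SOCS1, an inhibitor of JAK kinases (3.67 and 2.31). Epithelial-mesenchymal transition had 8 of 23, led by the receptor kinase AXL (3.50 and 2.26). Endocytosis with PD-L1 trafficking had 8 of 22, led by the clathrin adaptor subunit AP2S1 (3.41 and 2.40), and nuclear transport had 9 of 25, led by importin beta, KPNB1 (3.45 and 2.2). Basal breast markers had 4 of 13, led by ITGB4 (3.54 and 2.22), and luminal markers 5 of 14, led by ERBB2 (3.51 and 2.16). With windows of 5 kb, luminal markers passed with 12 of 14 genes (log2 odds ratio 2.50, exact adjusted p = 0.0183). Matching on local density was not run for these windows. With windows of 500 bp, luminal markers had 5 of 14 and did not pass (exact adjusted p = 0.853). Markers of other tissues did not pass either, with 7 of 18 genes for leukocytes (CD8A, 4.20 and 2.31), 4 of 17 for hepatocytes (F2, 3.55 and 2.12) and 6 of 16 for neurons (GRIN1, 3.37 and 2.45).

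Housekeeping lists had shares above that of all genes that did not pass. Glycolysis had 11 of 18 genes (61.1%, adjusted p = 0.0716, Fisher's exact test), with PGK1 first. Ribosomal proteins had 35 of 81 (43.2%, exact adjusted p = 0.173), led by RPL38 (fold 3.38 and 2.48), and proteasome subunits 18 of 39 (46.2%, adjusted p = 0.232), led by PSMD14 (3.54 and 2.97). With reciprocal overlap, proteasome subunits passed with 11 of 39 (log2 odds ratio 1.88, exact adjusted p = 0.00968). Very long fragile-site genes had 2 of 15 (13.3%, adjusted p = 0.389, exact), with DLG2 first (3.48 and 2.03). In replicate 1 alone, 3 lists passed that did not with shared regions: ribosomal proteins (log2 odds ratio 1.98, adjusted p = 5.1e-05, exact), endocytosis (2.70, 0.0162) and, depleted, MHC class I (−2.44, 0.00174). Against lists matched on local density, the ribosomal call was kept (adjusted permutation p = 0.00105), and those for endocytosis (95.5% against 76.3%, 0.0924) and MHC class I (27.8% against 53.9%, 0.0764) were lost.

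**Figure D2:**
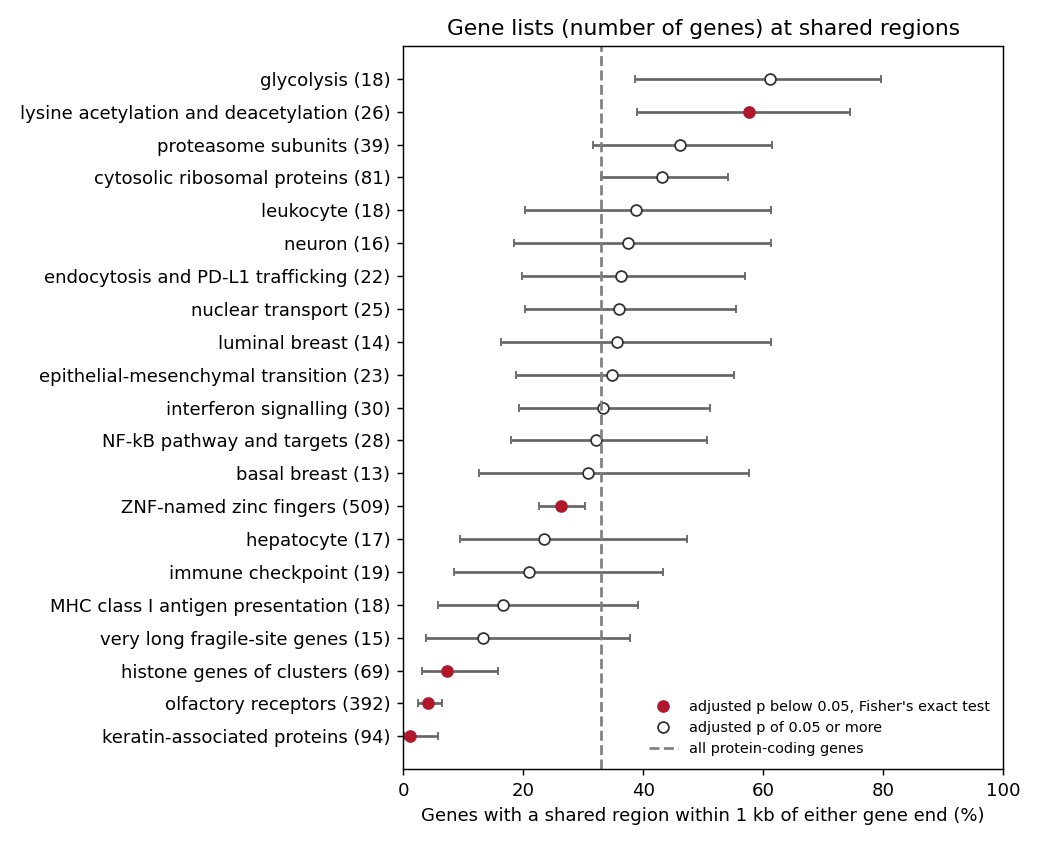
Share of the genes of each of 21 lists with a shared region within 1 kb of either gene end (horizontal axis, percent); bars are Wilson 95% intervals, numbers in brackets are genes, and the dashed line is the share of all protein-coding genes (32.9%). Filled points passed Fisher's exact test after adjustment; olfactory receptors sit at 4.08% and lysine acetylation at 57.7%.

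Over gene bodies, 3 of the families depleted at gene ends were depleted too. Olfactory receptors had a shared region in 6.12% of genes, against 30.2% in random lists matched on gene length. Keratin-associated proteins had 1.06% against 13.3%, and ZNF zinc fingers 39.7% against 52.1%. Each had an adjusted permutation p of 0.0014, and no other list of the 21 passed. Of all protein-coding genes, 48.9% had a shared region in the body. Among lists that did not pass, glycolysis had 77.8% against 48.6% (adjusted permutation p = 0.0857), lysine acetylation 73.1% against 54.2% (0.271) and MHC class I 27.8% against 44.6% (0.578). The keratin-associated call was lost with the peaks of higher fold (0% against 3.59%, adjusted permutation p = 0.358), reciprocal overlap (1.06% against 3.22%, 0.767) and replicate 2 alone (4.26% against 12.6%, 0.0658). The ZNF call was lost with the peaks of higher fold (14.9% against 19.3%, 0.113). With matching on gene length and local density, both passed with the peaks of higher fold (adjusted permutation p = 0.0126 for keratin-associated proteins and 0.0042 for ZNF genes). Keratin-associated proteins then also passed in replicate 2 alone (0.0014), but not with reciprocal overlap (0.233). In replicate 1 alone, MHC class I (0.00315, depleted), epithelial-mesenchymal transition (0.0413) and ribosomal proteins (0.0014) passed, as did glycolysis (0.0479) and, depleted, histone genes (0.0479) with equal numbers of peaks. With matching on local density as well, MHC class I (33.3% against 56.1%, adjusted permutation p = 0.0903), glycolysis (72.2% against 46.1%, 0.123) and histone genes (2.90% against 6.56%, 0.606) did not pass, and the other 2 did. Ribosomal proteins had 88.9% against 65% in replicate 1 alone and 35.8% against 41.3% in replicate 2 alone.

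The fourth comparison asked how peaks were spread over chromosomes. Chromosome 20 had the highest density, with 146 peaks per Mb in replicate 1 and 92.5 in replicate 2, followed by chromosome 19 with 140 and 77. Chromosome X had the lowest, with 1.56 and 3.21 peaks per Mb, so that chromosomes 20 and X differed 94.1-fold and 28.8-fold. X held 25 shared regions, the PGK1 region among them, and chromosome 20 held 3828. Across 23 chromosomes the densities of the replicates had a Pearson's r of 0.98 and a Spearman's rho of 0.975 (adjusted permutation p = 2.5e-05 for both, 5 relations tested), and r was 0.968 without the 2 chromosomes farthest from the median. Density also followed the number of protein-coding genes per Mb, with rho 0.776 in replicate 1 (adjusted permutation p = 5e-05; r 0.705, adjusted p = 0.0003) and 0.806 in replicate 2 (2.5e-05; r 0.685, adjusted p = 0.00162). Without the 2 farthest chromosomes, r was 0.565 and 0.624. Density against the median implied background had rho 0.539 in replicate 1 (adjusted permutation p = 0.00914; r 0.55, adjusted p = 0.00748) and 0.766 in replicate 2 (6.25e-05; r 0.798, adjusted p = 2.5e-05), with r 0.388 and 0.597 without the 2 farthest.

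**Figure D3:**
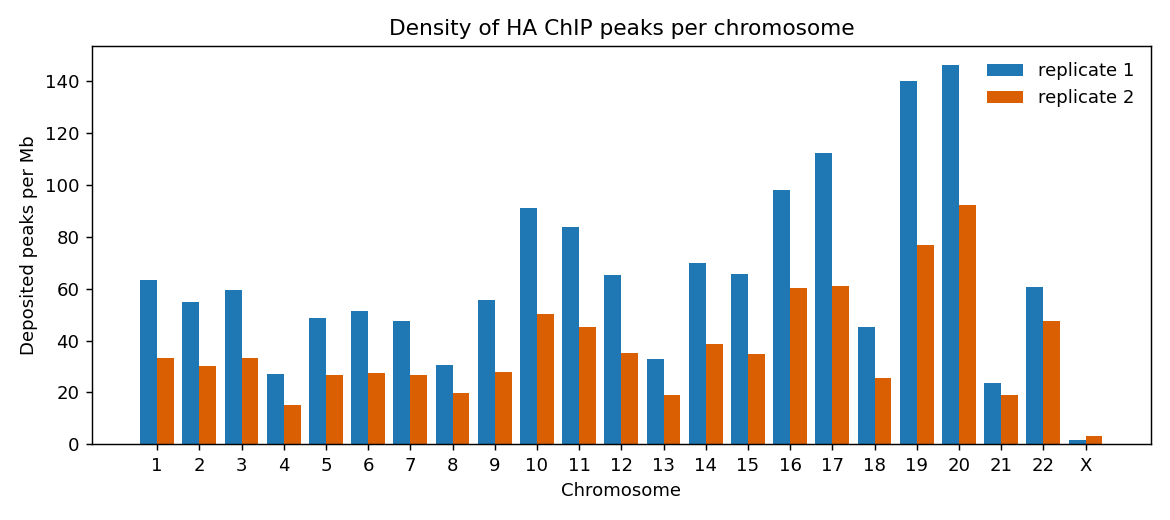
Deposited peaks per Mb of sequence considered (vertical axis) on each chromosome (horizontal axis) in replicates 1 and 2; each bar is 1 chromosome in 1 replicate, with no error. Chromosome 20 reaches 146 and 92.5 peaks per Mb, and chromosome X 1.56 and 3.21.

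Chromosomes 20 and 16 held most of the widest shared regions. The widest, 42190 bp at 20:62528910-62571099, overlapped no protein-coding gene and lay 52915 bp from GATA5. The next, 37780 bp at 20:62785969-62823748, covered parts of MRGBP, OGFR and COL9A3. Of the 100 widest regions, 36 were on chromosome 20, 25 on chromosome 16, 13 on chromosome 3, 8 on chromosome 17 and 2 on chromosome 19. Outside chromosome 20, the widest lay at 16:88859580-88889135 over TRAPPC2L, PABPN1L and CBFA2T3, and at 3:48572940-48601722 over COL7A1 and UQCRC1. Fold enrichment in the 20:62528910-62571099 region was 3.36 in replicate 1 and 2.04 in replicate 2.

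The last comparison looked at the gene of the precipitated protein. CD274 (9:5450542-5470554) held no peak in either replicate. The nearest peaks of replicate 1 were at 9:4836230-4836579, 614 kb below the gene, and at 9:5650303-5650683, 180 kb above it. Replicate 2 had peaks nearer, at 9:5437377-5438385, 12.2 kb below (fold 2.67), and at 9:5534590-5534980, inside PDCD1LG2, the gene of the ligand PD-L2 (fold 2.48). JAK2, the kinase gene on the lower side, held no peak in either replicate. Within 500 kb of CD274 there were 3 peaks in replicate 1 and 4 in replicate 2. A list of peaks above a threshold sets no upper limit on binding at CD274.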

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

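The rule behind this part counts any signal outside chromosomes 1 to 22 and X above 3 peaks, with no test of a cause. On an unlocalised contig of chromosome 14, outside the comparisons, there were 24 peaks in replicate 1 and 17 in replicate 2, with folds of up to 3.61 and 3.15. A contig of chromosome 17 held 9 peaks in replicate 1 and 4 in replicate 2. Mitochondrial DNA held 4 peaks in replicate 1 with folds of 1.74 to 2.31 and a −log10 q of up to 218, and 3 peaks in replicate 2 with a −log10 q of up to 3.29. Chromosome Y held 5 peaks in replicate 1, with a −log10 q of up to 1.87, and 0 in replicate 2.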

How the results depend on the processing

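Moves of 20 to 100 kb and lists matched on local density were chosen after the results were seen; the other alternatives were fixed before the data were examined. The overlap of replicates stayed above placement, with ratios of 3.53 to 7.92 to random placement and 2.03 to 3.86 to moved peaks, where a ratio could be had. So did gene ends, with ratios of 1.95 to 3.42 and 1.29 to 2.14. The number of shared regions was 1 at a −log10 q of 5 and 9151 with the 50% of peaks of higher fold. It was 15699 with reciprocal overlap and 29509 with equal numbers of peaks. Each setting asks for more overlap or uses fewer peaks. At a −log10 q of 5, 1 of the 40 peaks of replicate 1 (2.5%) overlapped 1 of the 69 of replicate 2, against 28.7% of all its peaks. That 1 region was the one at PGK1 (−log10 q of 5.70 and 15.6). With 1 region, the setting of a −log10 q of 5 gave no value for fold, location or lists. Spearman's rho of fold was 0.0137, 0.122 and 0.236 in the other 3; the cause was not tested. The share inside protein-coding genes went to 0.995 times the share of moved regions, which lie near genes too. It was below the moved share with the peaks of higher fold (ratio 0.942), windows of 5 kb (0.953), overlap in place of centres (0.968), reciprocal overlap (0.971) and replicate 1 alone (0.984). Each of these had a two-sided permutation p of 0.0198. With equal numbers the ratio was 0.988 (permutation p = 0.0396), and in replicate 2 alone it was 0.999 (0.812). Gene lists passing at gene ends numbered 2 with the peaks of higher fold, 3 with equal numbers, 3 when matched on density and 4 to 6 with 1 replicate alone, against 5. Over bodies they numbered 1 with the peaks of higher fold, 5 with equal numbers and 2 to 6 with 1 replicate alone, against 3; the cause was not tested. Reciprocal overlap turned the log2 odds ratio of ZNF genes to 0.19 (adjusted p = 0.779, exact), and the ZNF call at gene ends was lost with the peaks of higher fold (log2 odds ratio −0.11, adjusted p = 0.785, exact), equal numbers (−0.39, 0.0583) and replicate 1 alone (−0.20, 0.279), against −0.47. Lysine acetylation passed with reciprocal overlap (adjusted p = 0.0146, exact) and windows of 5 kb (0.0109). With reciprocal overlap and matching on local density it did not (30.8% against 11.3%, adjusted permutation p = 0.0525). Histone genes did not pass with the peaks of higher fold (log2 odds ratio −0.66, adjusted p = 0.785, exact) or reciprocal overlap (−1.57, 0.272), against −2.53. Olfactory receptors and keratin-associated proteins passed at gene ends in all 8 alternatives. Leaving out peaks near assembly gaps, and the settings for motifs, were not run. No paired analysis was possible because each list already sets a ChIP against input, and no comparison between groups was made.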

Other observations

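The tests in this part were chosen after the result was seen, except that of read depth in replicate 2 against the number of peaks in 5 Mb bins. Transfer RNA genes were a class at which the replicates differed in extent. Of 443 tRNA genes, 214 (48.3%, Wilson 95% interval 43.7% to 53%) had a peak of replicate 1 within 500 bp, against 15.9% when the genes were moved by 20 to 100 kb (adjusted permutation permutation p = 0.005). In replicate 2 there were 53 (12.0%), against 7.33% (adjusted permutation p = 0.005), and 48 genes had a peak of both replicates. The median fold of peaks at tRNA genes was 3.87 in replicate 1 and 2.26 in replicate 2. MicroRNA genes had 36.1% against 21.1% in replicate 1 and 14.7% against 10.4% in replicate 2 (adjusted permutation p = 0.005 for both). Small nuclear RNA genes had 12.3% against 15.2% in replicate 1 (adjusted permutation p = 0.402) and 2.60% against 7.73% in replicate 2 (0.02), and small nucleolar RNA genes 14.6% against 16.4% (0.0913) and 6.69% against 8.21% (0.0699).

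A stretch of chromosome 9 around CDKN2A, CDKN2B and MTAP held no peaks, from 20624143 to 26189158 in replicate 1 (5565 kb) and from 19408610 to 26220060 in replicate 2 (6811 kb). CDKN2A, a cell cycle inhibitor gene, is known to be deleted in MDA-MB-231.

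For the peaks of replicate 1 at tRNA genes, a high density of peaks around these genes stays open. The share of 48.3% was above the 20.8% reached by the highest of the moves, so it exceeded that at the distances of the moves. This cannot decide it, since the pattern was found by the same comparison. Density of peaks nearer to the genes than the moves was not measured. Whether the same enrichment was missed in replicate 2 for lack of depth stays open. At the median implied background of replicate 2, a fold of 3.87 would have a −log10 p of 14, where the list starts at 3.29. This cannot decide it, since folds were lower in the list of replicate 2 (median 2.27, against 3.14 in replicate 1). The 3.87 also came from peaks that had passed in replicate 1, and the background was not measured at tRNA genes. Recovery of open, highly transcribed chromatin without the target stays open and cannot be told apart from binding, because no mock precipitation was analysed here; a ratio of 0.813 at small nuclear RNA genes in replicate 1 decides nothing for tRNA genes. Binding near tRNA genes in replicate 1 is thus a hypothesis.

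For the strong peaks of replicate 2 in JARID2, AEBP2 and MTF2, whether binding at that strength was present in both replicates stays open. At an implied background of 2.6 (the 5% point of replicate 1), 9 of the 20 peaks would reach a −log10 p of 7.11 by their own fold. A −log10 q of 4 needed that p in replicate 1, and 0 of the 9 overlapped such a peak. This cannot decide it, since the genes were chosen by their high values in replicate 2. The low values of replicate 1 were known before, and the background was not measured at these loci. Of the 20 peaks, 6 overlapped any peak of replicate 1. The other 11 peaks would not pass in replicate 1 by their own fold. A higher copy number of the loci stays open too. Strong peaks per kb in flanks of 500 kb were 0.0151 of those inside, but the genes were chosen by the peaks inside them. A candidate explanation that stays open is DNA of cDNA constructs in the library of replicate 2, which would put the 20 peaks on exons; no exon coordinates were used here, so this could not be tested. No biological explanation was tested, since the design names no difference between the replicates.

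For the differences in peak density between chromosomes, gene density alone is argued against. Chromosomes next to each other in gene density differed by a median of 1.34-fold in peaks per Mb in both replicates (22 pairs). Read depth, copy number included, may contribute in replicate 2: across 5 Mb bins within a chromosome, peaks and implied background had a median rho of 0.707, above 0 in 21 of 22 chromosomes. In replicate 1 the median was −0.0694, above 0 in 9 of 21 chromosomes and from −0.606 to 0.646, while across chromosomes rho was 0.539, which leaves depth open there. No biological explanation was tested, since the design has a single cell line.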
